A study of Macaca mulatta with 24 samples.

How the data were processed

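Endometrial RNA from rhesus monkeys was measured on 24 Agilent 1-colour microarrays, 12 from conception cycles and 12 from cycles without mating. Each cycle type had 4 arrays at each of days 2, 4 and 6 after ovulation. The source names of the conception arrays give the day as post fertilization, whereas their descriptions give it as after ovulation, which is used here. Per the labels' protocols, RNA was extracted with Trizol and Cy3-labelled cRNA was made from 200 ng of total RNA. The titles of 8 non-mated samples name day 2, whereas their source name, description and characteristics give day 4 or day 6, and these other labels were used. Nothing in the labels says that the arrays of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

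The deposited scanner files hold a fluorescence intensity per spot in linear units, background-corrected by Agilent Feature Extraction per the file headers. The headers name version 9.5.3.1 and the submitters' processing notes name 10.7.3.1. The headers also give the slide, the scan day and the scan range, here numbered as slides 1 to 9 and scan days 1 and 2. On slides 4 and 8, 6 arrays were scanned over a single range, and the others over an extended range. Of the 6 arrays only non-mated day 2 replicate 2 came from a non-mated cycle, so the scan range partly goes with the cycle type. On scan day 1 the conception arrays lay on slides 7 and 8 and the non-mated arrays on slides 5 and 6. Slide and cycle type can therefore not be told apart within that scan day. The authors also deposited a value table on the log2 scale, whose columns correlated with differences between arrays in the scanner values at r from 0.995 to 1.00. Its column medians, for replicates 1 to 4, were -0.354, -0.307, -0.406 and -0.252 at conception day 2, -0.196, 0.0291, 0.0741 and -0.250 at conception day 4, and 0.105, 0.0160, -0.364 and -0.0738 at conception day 6. For non-mated cycles they were -0.238, -0.280, 2.85 and -0.335 at day 2, 0.698, 2.12, -0.396 and -0.403 at day 4, and -0.141, -0.302, -0.303 and -0.199 at day 6. The baseline on which the authors centred that table stays unknown, and it served only as an alternative source of values.

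Control spots were left out, and spots flagged as outliers were dropped unless all spots of the probe were flagged. The spots kept, of the 2 for each of 20217 probes, were averaged. A probe counted as well above background if any spot kept was. Conception day 6 replicate 3 had 616 flagged spots, and the other arrays had at most 50. The log2 processed signal minus the 75th percentile of its array was the level used throughout. Probes were kept if well above background on at least 3 of 4 arrays of at least 1 group, which left 12780 probes. For a gene with more than 1 probe the probe with the highest mean over all arrays was used, and a probe without a gene symbol was tested on its own. This gave 12197 features, 7922 of them with a symbol and 4275 without.

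Gene symbols were found for 12302 probes, of which 8208 carried a gene name in the files, 3680 were named through a gene ID and 216 through a transcript accession in the RefSeq gene table, 135 from a symbol in the description and 63 from a full gene name in the description. The RefSeq table was used for names only, and its coordinates were not used because the array files give positions on the rheMac2 build. The 63 full names were matched with a table written by hand for genes of the fixed lists alone, and the symbols of 52 probes were brought up to date with a second hand-written table. The effect of these tables on the list results was not computed. A further 251 symbols were updated through synonyms, and 392 without a match kept the name in the files.

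Group means of the 6 groups were fitted in 1 model with limma 3.58.1 (lmFit and eBayes, R 4.3.3), which left 18 residual degrees of freedom. Contrasts compared conception with non-mated cycles on each day and averaged over the days, day 6 with day 2 within each cycle type, the effect of day by F-test, and the interaction of cycle type and day. P-values were adjusted by the Benjamini-Hochberg method and the threshold was 0.05. All tests were two-sided.

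For the 33 gene lists, limma's camera was used with a preset correlation of 0.01, and 29 lists with at least 4 measured genes were tested. Camera with an estimated correlation and fry were run beside it. Fry asks whether the genes of a list move, on balance, 1 way, or in its mixed form either way, and neither form compares the list with other genes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the plots.

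Genes are named by a rule. For each comparison of cycle types, these are the 10 highest and 10 lowest log2 differences among genes past the threshold whose arrays do not overlap, or, where fewer than 5 passed in a direction, the 5 smallest p-values in it, given as values and not as changes. For day 6 against day 2 they are the 8 highest and 8 lowest among genes past both the day F-test and the contrast, without overlap of the arrays. For the interaction they are the 8 smallest p-values, and for each list up to 4 members with the smallest p-values. PGR, ESR1, PAEP, LIF, IGFBP1, PRL, SPP1, MKI67, HAND2 and FKBP5 were to be given in any case. Of these, PGR, ESR1, HAND2 and FKBP5 are not analysed here, and IGFBP1, PRL and MKI67 were well above background on 2, 1 and 1 arrays and did not pass the filter. Not every gene that the rule names is reported here.

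The groups, contrasts, tests, lists, naming rule and most alternatives were chosen before the data were examined. The alternatives covered background correction, normalization, the filter on dim probes, the choice of probe, array weights, the prior variance, blocks for slide, scan day and replicate number, the source of values, the threshold, the samples in the fit, and leaving out each array in turn. Fits without 3 arrays of low signal, called weak arrays, were added after seeing the data. Counts from fits without the weak arrays are given beside the others because these arrays belong to non-mated cycles only.

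The procedure was tested on simulated data in which 200 of 12197 features were changed. Features were drawn independently with the same spread on every array, so no simulated array was weak and recovery on the real arrays can differ. False calls with all arrays were 0 of 17 for the first comparison below and 1 of 29 for the second. Without the weak arrays they were 5 of 90 and 0 of 80. For conception against non-mated at day 6, 1% of features changed by a log2 of 1 and 16% of those changed by a log2 of 2 were recovered with all 24 arrays, against 17% and 68% without the weak arrays. For day 6 against day 2 in conception cycles the shares were 3% and 25% with all arrays and 11% and 69% without the weak arrays. The number of arrays limits the precision of all values.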

Results

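The endometrium, the lining of the uterus that receives the embryo, was sampled 2, 4 or 6 days past ovulation, both in cycles that led to conception and in cycles without mating. Each of the 6 groups held 4 arrays. The 75th percentile of the signal ranged from 23.1 to 5421 between arrays. Between 53.3% and 71.5% of probes were well above background on 21 arrays. On 3 non-mated arrays the share was lower, at 4.33% for day 2 replicate 3, 37.9% for day 4 replicate 1 and 21.8% for day 4 replicate 2. The first principal component, with 45.6% of the variance, set 2 of these weak arrays apart, day 2 replicate 3 at -0.71 and day 4 replicate 2 at -0.61, while day 4 replicate 1 lay at -0.07 and the other arrays between -0.01 and 0.15. The second component held 11.2%. Among the 276 pairs of arrays the highest correlation was 0.975 and 0 pairs were identical. Non-mated day 2 replicate 3 correlated at most at 0.381 with an array that was not weak.

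**Figure D1:**
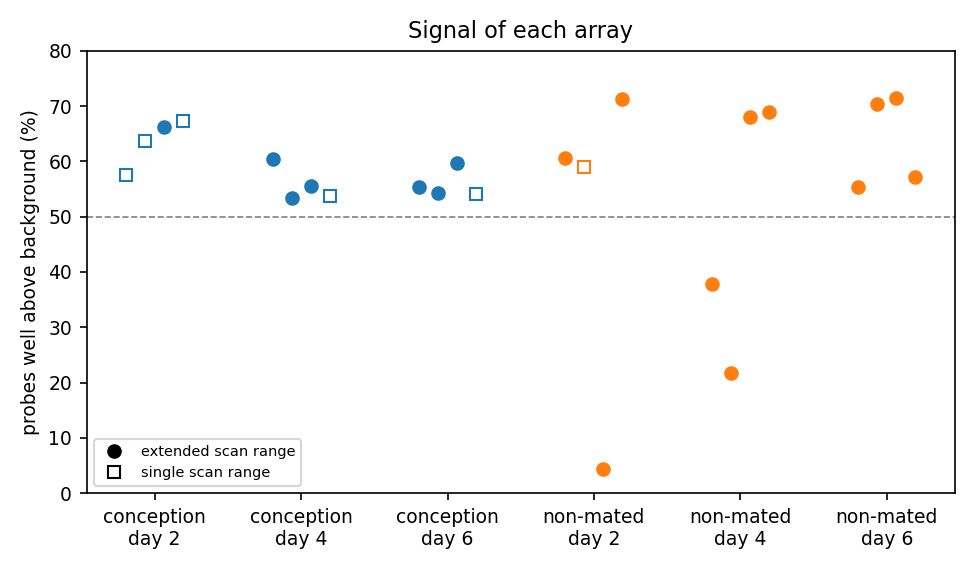
Percent of probes well above background (vertical axis) for each of the 24 arrays by group; squares are arrays scanned over a single range, and the dashed line is at 50%. The 3 weak arrays lie at 4.33%, 21.8% and 37.9%, below the 53.3% to 71.5% of the others.

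The first question was whether endometrium of conception cycles differed from that of non-mated cycles on each day. At day 2 IL6, which encodes an inflammatory cytokine, was among the genes lower in conception cycles with the smallest p-values. Its log2 difference was -3.74 ± 1.04 (SE, n = 4 against 4, limma adjusted p = 0.792). The other genes with the smallest p-values on the lower side were the lysosomal ion channel gene MCOLN3 at -2.37 ± 0.69, CYRIA at -1.55 ± 0.48, MAIP1 at -1.32 ± 0.41 and the adhesion molecule gene NRCAM at -1.85 ± 0.58. On the higher side they included LYZ, which encodes lysozyme, at 1.58 ± 0.59, CDC42EP1 at 1.15 ± 0.43, NDRG2 at 1.11 ± 0.40 and ILK, which encodes integrin-linked kinase, at 0.96 ± 0.37. PAEP, which encodes glycodelin, lay at -1.34 ± 0.79, LIF, a cytokine gene needed for implantation in mice, at -1.51 ± 0.94, and SPP1, which encodes osteopontin, at 0.64 ± 1.25. In the fit without the weak arrays CDC42EP1 lay at 0.74, ILK at 0.48, MAIP1 at -0.88, LIF at -0.73 and SPP1 at 1.07. The median of all genes at day 2 was -0.15, and it became 0.16 with normexp correction and 0.49 with quantile normalization, against which camera compares each list. By limma, 0 genes passed, 305 had an unadjusted p under 0.05 where chance gives about 610, and without the weak arrays 0 passed and 149 had an unadjusted p under 0.05.

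Several fixed lists were shifted at day 2 by camera, but 0 passed with an estimated correlation, and values that moved by over 1.5 times without the weak arrays are given for both fits. Nuclear-encoded oxidative phosphorylation genes were higher for 19 of 20 members, with a median log2 difference of 0.43 (adjusted p = 0.000188, adjusted p = 0.534 with an estimated correlation). Without the weak arrays their camera direction turned to lower, with a median of -0.04, SDHA at 0.25 in place of 0.88 and COX4I1 at 0.15 in place of 0.65. Genes of the secretory pathway and unfolded protein response were higher for 16 of 20, with a median of 0.41 (adjusted p = 0.00138, adjusted p = 0.498 with an estimated correlation). Their median was 0.03 without the weak arrays, with ATF4 at 0.40 in place of 0.94 and SEC61A1 at 0.28 in place of 1.10. Cell cycle genes were higher for 16 of 22, with a median of 0.30 (adjusted p = 0.0388, adjusted p = 0.847 with an estimated correlation), and the median was 0.53 without the weak arrays. PCNA lay at 0.67 with and 0.29 without them, and MCM7 at 0.62 and 0.29. Immediate early and heat shock genes were higher for 9 of 12, with a median of 0.39 (adjusted p = 0.031, adjusted p = 0.284 with an estimated correlation), IER3 at 0.99 with and 0.52 without the weak arrays and DNAJB1 at 0.85 and 0.16.

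Glycolysis and hypoxia genes were higher at day 2 for 12 of 17, with a median of 0.49 (adjusted p = 0.0207, adjusted p = 0.498 with an estimated correlation). The median was 0.24 without the weak arrays, with HK2 at 0.76 in place of 1.45 and TPI1 at 0.30 in place of 0.61. Extracellular matrix and protease genes were higher for 16 of 18, with a median of 0.37 (adjusted p = 0.0382, adjusted p = 0.534 with an estimated correlation), COL6A3 at 0.90 with and 0.59 without the weak arrays and COL4A1 at 0.54 and 0.11. Progesterone receptor pathway genes were higher for 15 of 19, with a median of 0.29 (adjusted p = 0.031, adjusted p = 0.541 with an estimated correlation). Their median was -0.02 without the weak arrays, with PER1 at 0.28 in place of 1.19 and BMP2 at -0.36 in place of -0.84. Epithelial markers were higher for 7 of 9, with a median of 0.66 (adjusted p = 0.031, adjusted p = 0.534 with an estimated correlation), which was 0.04 without the weak arrays, where CLDN3 went from 0.77 to 0.04 and PAX8 from 0.82 to 0.29. Cytokine and chemokine genes were lower for 11 of 13, with a median of -0.86 (adjusted p = 0.0388, adjusted p = 0.534 with an estimated correlation) that was -0.09 without the weak arrays, where LIFR went from -1.55 to -0.67. The cytokine median turned to 0.11 with normexp correction and 0.22 with quantile normalization. Quantile normalization ended the call of all 9 lists (adjusted p from 0.389 to 0.919), and normexp those of the progesterone receptor (0.276), cytokine (0.369) and epithelial (0.188) lists. No member of these lists passed over all genes, and adjusted over the list alone 1 cytokine gene passed and 0 genes of the others.

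On slide 4, which held 2 conception arrays and 1 non-mated array at day 2 and no weak array, the mean difference was 0.05 for oxidative phosphorylation, 0.05 for the secretory list, 0.41 for cell cycle, 0.61 for immediate early and heat shock, -0.01 for glycolysis, 0.07 for extracellular matrix, 0.03 for the progesterone receptor pathway, 0.19 for epithelial markers and -0.24 for cytokines. On scan day 1, with the weak array, and scan day 2, without it, the oxidative phosphorylation means at day 2 were 0.82 and -0.02, and the cell cycle means -0.33 and 0.92. The cycle types lay on different slides on scan day 1. Of the 9 lists, only glycolysis passed with the slide as a block (adjusted p = 0.00294, adjusted p = 0.497 with an estimated correlation), and the cell cycle list turned to lower (adjusted p = 0.319). Metallothioneins also passed there as higher (adjusted p = 0.00997, adjusted p = 0.497 with an estimated correlation). Of the same 9 lists, cell cycle (adjusted p = 0.0118, adjusted p = 0.845 with an estimated correlation) and immediate early genes (adjusted p = 0.0118, adjusted p = 0.378 with an estimated correlation) passed in the fit without the weak arrays. Macrophage markers passed as well in that fit, with 9 of 10 higher and a median of 0.40 (adjusted p = 0.00437, adjusted p = 0.378 with an estimated correlation), against a median of -0.02 with all arrays. The 9 lists became 5 without conception day 2 replicate 1, 4 without conception day 2 replicate 4, 5 without non-mated day 2 replicate 1 and 5 without non-mated day 2 replicate 4.

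At day 4 the calcium-binding protein gene TESC had a log2 difference of 2.30 ± 0.47 (SE, n = 4 against 4, limma adjusted p = 0.272) and GADD45A, a stress-induced growth arrest gene, of 2.65 ± 0.55 (adjusted p = 0.272). ARID5B lay at 1.56 ± 0.35, IFI30, which encodes a lysosomal thiol reductase, at 1.90 ± 0.47 and MTARC2 at 1.22 ± 0.32. Other probes differed by less, at 1.08 for ARID5B and at 0.68 and 0.74 for MTARC2. On the lower side FSTL3, which encodes an activin-binding protein, lay at -2.65 ± 0.55 (adjusted p = 0.272) and PIWIL4, an Argonaute family gene of the piRNA pathway, at -2.46 ± 0.48 (adjusted p = 0.272). HRH1, the histamine H1 receptor gene, lay at -2.79 ± 0.61, MCF2 at -2.96 ± 0.69 and TMEM61 at -2.40 ± 0.57. Where a probe was not well above background on any array of the dimmer group, a floored fold is given. For it, levels of the dimmer group were raised to at least the lowest signal well above background on each array. It leaves out sampling error and other processing, so the true fold can be smaller. The levels in conception cycles were lower by a floored fold of 3.65 for HRH1, 3.06 for MCF2 and 3.41 for TMEM61. PAEP lay at 1.17 ± 0.79, LIF at 0.71 ± 0.94 and SPP1 at 1.63 ± 1.25. In the fit without the weak arrays MTARC2 lay at 0.80 and LIF at 1.77. By limma, 0 genes passed and 743 had an unadjusted p under 0.05, and without the weak arrays 0 passed and 666 had an unadjusted p under 0.05. Without non-mated day 4 replicate 3 the count was 1.

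Oxidative phosphorylation genes were higher for 20 of 20 members at day 4, with a median log2 difference of 0.42 (camera adjusted p = 0.00373, adjusted p = 0.807 with an estimated correlation), ATP5PO at 0.92 and NDUFV2 at 0.86 (0.52 without the weak arrays). Macrophage markers were higher for 7 of 10, with a median of 0.73 (adjusted p = 0.036, adjusted p = 0.656 with an estimated correlation), CD68 at 1.14 and the complement gene C1QA at 1.13 (0.41 without the weak arrays). Over all genes 0 members passed, and adjusted over the list alone 0 passed in both lists. Slides 2 and 3 each held 1 array of each cycle type, with the weak array on the non-mated side. The oxidative phosphorylation means there were -0.16 and 1.09, and the macrophage means 0.45 and -0.41. Quantile normalization moved the median of all genes from 0.02 to 0.41 at day 4 and ended both calls, with an adjusted p of 0.273 for oxidative phosphorylation and 0.0621 for macrophage markers, whose median became 1.24. On scan days 1 and 2 these means were 0.45 and 0.47 for oxidative phosphorylation, and 1.02 and 0.02 for macrophage markers. The adjusted p with the slide as a block was 0.583 for oxidative phosphorylation and 0.017 for macrophage markers (adjusted p = 0.596 with an estimated correlation). Receptivity genes, metallothioneins and complement passed there as higher and cell cycle as lower, and with an estimated correlation the smallest adjusted p was 0.398. The fit without the weak arrays left only replicates 3 and 4 of non-mated day 4. Both were scanned on scan day 1, on slides 5 and 6, which held no conception array, so cycle type and slide cannot be told apart within day 4. In that fit the macrophage markers were higher for 10 of 10, with a median of 1.03 (adjusted p = 1.6e-06, adjusted p = 0.172 with an estimated correlation). In that fit 8 lists passed in place of 2, and 0 with an estimated correlation. Markers of other cell types were among them, with medians of 0.80 for natural killer cells (adjusted p = 0.0104), 0.50 for endothelium (adjusted p = 0.0115) and 1.05 for T and B cells (adjusted p = 0.0327). The others were oxidative phosphorylation (0.30, adjusted p = 0.00764), ribosomal proteins (0.66, adjusted p = 1.17e-05), extracellular matrix (0.64, adjusted p = 0.0145) and, lower in conception cycles, cholesterol synthesis (-0.48, adjusted p = 0.00269). Each of these 7 had an adjusted p of 0.492 with an estimated correlation. With all arrays the medians were -0.02 for natural killer cells, 0.14 for endothelium, 0.70 for T and B cells, 0.20 for ribosomal proteins, 0.40 for extracellular matrix and 0.02 for cholesterol synthesis, and none of these 6 lists passed. The 2 lists became 4 without conception day 4 replicate 3 and 6 without non-mated day 4 replicate 2.

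At day 6 PIWIL4 was lower in conception cycles, with a log2 difference of -2.98 ± 0.48 (SE, n = 4 against 4, limma adjusted p = 0.0338). Its probe lies on chromosome 14 from 93162324 to 93162383 (rheMac2). The level was -4.46 ± 0.86 (SD, n = 4) in conception cycles, where it was well above background on 0 arrays, and -1.48 ± 0.18 in non-mated cycles. The floored fold was 6.09. Over the alternatives the log2 difference ranged from -3.22 to -1.59, so the size is uncertain. The other 4 lowest p-values on the lower side included TMEM61, a transmembrane protein gene, at -3.04 ± 0.57 (adjusted p = 0.142) and TEX29 at -4.62 ± 0.89 (adjusted p = 0.142). The rest were CFAP100, a cilia and flagella associated gene, at -2.69 ± 0.56 (adjusted p = 0.207), and HRH1 at -2.74 ± 0.61 (adjusted p = 0.371, floored fold 2.23). On the higher side NIPAL1 lay at 2.68 ± 0.86, ITGA2B at 1.41 ± 0.49, WDR72 at 1.75 ± 0.64, KIAA0562 at 1.31 ± 0.50 and WDR4 at 0.93 ± 0.36 (adjusted p = 1.00 each). PAEP lay at -0.11 ± 0.79, LIF at 0.17 ± 0.94 and SPP1 at -0.17 ± 1.25.

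By limma, 1 gene passed at day 6 and 291 had an unadjusted p under 0.05. Without the weak arrays, none of which is a day 6 array, 3 passed (PIWIL4, TMEM61 and HRH1, adjusted p 0.0201, 0.0354 and 0.0354) and 1139 had an unadjusted p under 0.05. PIWIL4 differed by -2.81 on slide 1, which held 2 conception arrays and 1 non-mated array, by -3.22 on scan day 1 and by -2.74 on scan day 2. The cycle types lay on different slides on scan day 1, and scan day 2 includes the slide 1 arrays, so these values are not separate checks. With the slide as a block the PIWIL4 difference was -2.73 ± 0.61, with an adjusted p of 1.00. The adjusted p of PIWIL4 lay between 0.0520 and 0.283 when 1 array was left out from the following: non-mated day 6 replicates 1 to 4, conception day 6 replicates 2 and 3, conception day 2 replicates 2 and 4, conception day 4 replicates 1 and 4, non-mated day 2 replicates 1 and 4, and non-mated day 4 replicates 3 and 4. Without conception day 6 replicate 1 the count was 4, and without conception day 6 replicate 4 it was 2.

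**Figure D2:**
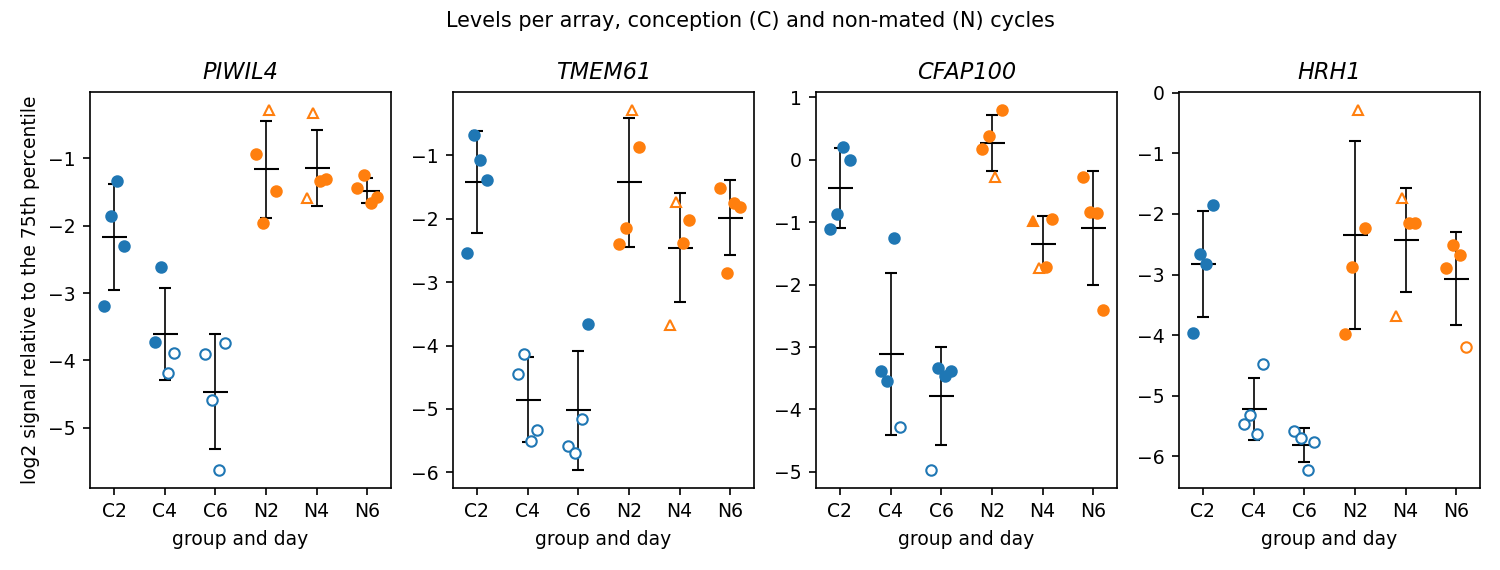
Level (log2 signal minus the array's 75th percentile, vertical axis) of PIWIL4, TMEM61, CFAP100 and HRH1 on each array by group; filled symbols are well above background, triangles are the weak arrays, and bars are the mean and SD of 4 arrays. PIWIL4 at day 6 averages -4.46 in conception and -1.48 in non-mated cycles.

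Among the lists at day 6, genes of the progesterone receptor pathway were lower in conception cycles for 16 of 19 members, with a median log2 difference of -0.67 (camera adjusted p = 0.000426, adjusted p = 0.748 with an estimated correlation). ZBTB16, a transcription factor gene induced by progesterone, lay at -2.92 ± 1.22 and WNT4 at -2.43 ± 1.04. Cell cycle genes were higher for 22 of 22, with a median of 0.68 (adjusted p = 4.72e-05, adjusted p = 0.748 with an estimated correlation). BIRC5, which encodes survivin, lay at 1.06 ± 0.72 and E2F1 at 1.11 ± 0.78. Cholesterol synthesis genes were lower for 15 of 15, with a median of -0.52 (adjusted p = 0.00766, adjusted p = 0.748 with an estimated correlation), LSS at -1.08 ± 0.52 and MVK at -0.75 ± 0.41. Ribosomal protein genes were higher for 12 of 15, with a median of 0.32 (adjusted p = 0.00511, adjusted p = 0.748 with an estimated correlation), RPS16 at 0.82 ± 0.46 and RPS19 at 0.63 ± 0.35. Over all genes and adjusted over the list alone, 0 members of these lists passed.

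Within slide 1, scan day 1 and scan day 2 the mean differences at day 6 were -0.94, -0.55 and -0.90 for the progesterone receptor pathway, 0.60, 0.86 and 0.62 for cell cycle, -0.52, -0.32 and -0.58 for cholesterol synthesis, and 0.01, 0.66 and -0.04 for ribosomal proteins. The scan day 1 values cannot be told apart from the slide, and scan day 2 includes the slide 1 arrays. A block for the slide gave an adjusted p of 4.52e-05 for the progesterone receptor pathway (adjusted p = 0.362 with an estimated correlation), 0.116 for cell cycle and 0.11 for cholesterol synthesis. For ribosomal proteins the direction turned, with an adjusted p of 0.758. Markers of immune cells passed with the block as higher in conception cycles, natural killer cells with an adjusted p of 4.53e-05, macrophages with 0.0109 and T and B cells with 0.00981, while prostaglandin genes (0.0303) and glycolysis (0.0495) passed as lower, each with an adjusted p of 0.362 with an estimated correlation. Without the block the natural killer markers were higher for 8 of 9, with a median of 0.48 (adjusted p = 0.0702, and 0.03 without the weak arrays, adjusted p = 0.836 with an estimated correlation). The macrophage median was 0.30 (adjusted p = 0.256) and that of T and B cells 0.43 (adjusted p = 0.258). With quantile normalization the ribosomal median was 0.02 (adjusted p = 0.39), and with normexp correction the cholesterol median was -0.34 and its call stayed (adjusted p = 0.000962). The 4 lists became 2 without non-mated day 6 replicate 3 and 8 without non-mated day 6 replicate 4.

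**Figure D3:**
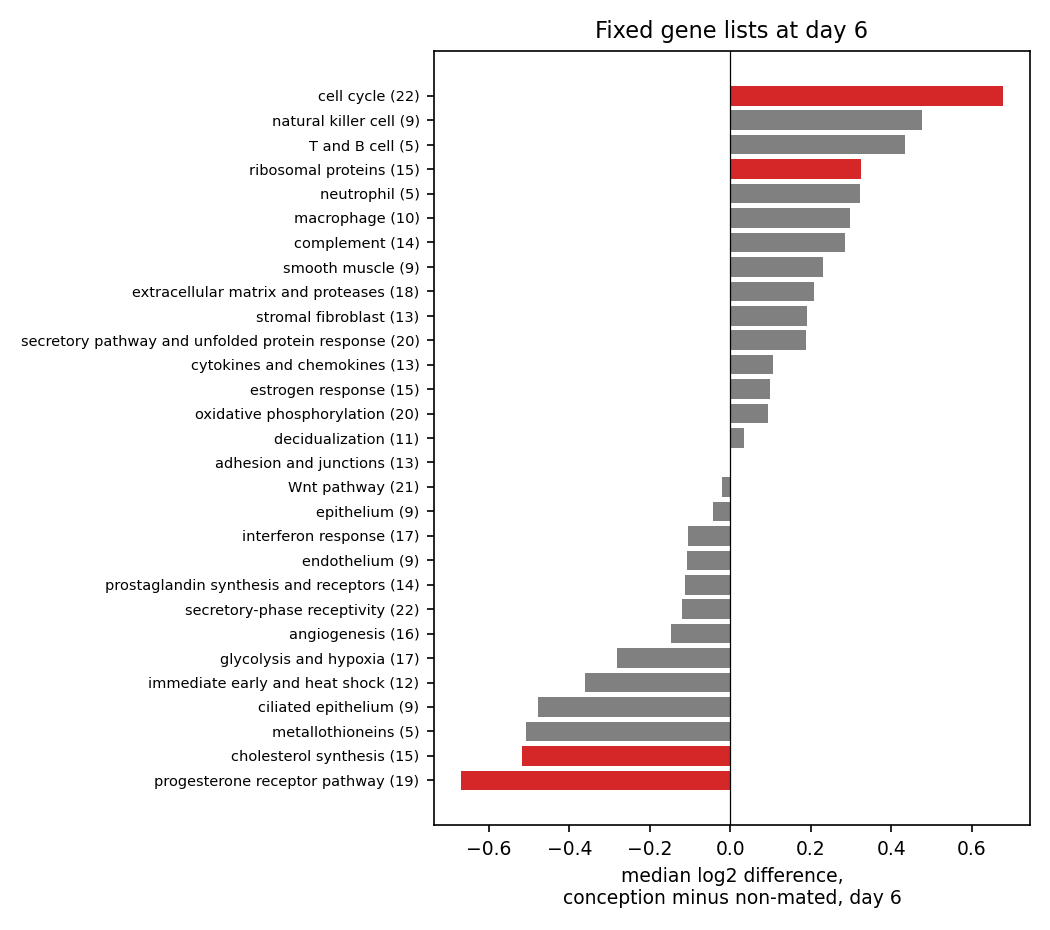
Median log2 difference between conception and non-mated cycles at day 6 (horizontal axis) for each tested list, with the number of measured genes in brackets; red bars passed camera at an adjusted p under 0.05. The red bars are at 0.68 for cell cycle, 0.32 for ribosomal proteins, -0.52 for cholesterol synthesis and -0.67 for the progesterone receptor pathway.

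The next comparison asked which genes differed between the cycle types on average over the 3 days, which does not require a difference on each day. PIWIL4 was lower in conception cycles, with a log2 difference of -2.15 ± 0.28 (SE, n = 12 against 12, limma adjusted p = 0.00109). It was well above background on 6 of 12 conception arrays and 9 of 12 non-mated arrays, so the size of the difference is uncertain, and with normexp correction it was -1.15 and did not pass. At day 2 alone PIWIL4 lay at -1.01, and at -0.71 ± 0.47 without the weak arrays, while TMEM61 lay at 0.01. HRH1 lay at -2.01 ± 0.35 (adjusted p = 0.0617), TMEM61 at -1.81 ± 0.33 (adjusted p = 0.0628), CFAP100 at -1.73 ± 0.32 (adjusted p = 0.064) and TEX29 at -2.54 ± 0.52 (adjusted p = 0.127). On the higher side TESC lay at 1.04 ± 0.27, the stress response gene IER3 at 1.12 ± 0.32, the serine protease gene HTRA1 at 1.02 ± 0.30, IFI30 at 0.91 ± 0.27 and GADD45A at 1.07 ± 0.32. PAEP lay at -0.09, LIF at -0.21 and SPP1 at 0.70, and without the weak arrays they lay at 0.05, 0.41 and 1.09. By limma 1 gene passed and 816 had an unadjusted p under 0.05, and without the weak arrays 2 passed and 938 had an unadjusted p under 0.05. PIWIL4 differed by -2.29 on scan day 1, where the cycle types lay on different slides, and -2.01 on scan day 2, and with the slide as a block by -1.74 ± 0.42 (adjusted p = 1.00). The count was 2 without conception day 2 replicate 4, conception day 4 replicate 3, conception day 6 replicate 1 or non-mated day 2 replicate 3. It was 3 without non-mated day 2 replicate 1, and 4 without conception day 6 replicate 4, non-mated day 2 replicate 2, non-mated day 4 replicate 1 or non-mated day 6 replicate 4.

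Oxidative phosphorylation genes were higher in conception cycles for 20 of 20 members over the 3 days, with a median log2 difference of 0.32 (camera adjusted p = 1.37e-05, adjusted p = 0.529 with an estimated correlation). Their median was 0.12 without the weak arrays, where NDUFB9 went from 0.36 to 0.13, and COX4I1 lay at 0.42 with all arrays. Secretory pathway genes were higher for 18 of 20, with a median of 0.31 (adjusted p = 0.000598, adjusted p = 0.529 with an estimated correlation) that was 0.11 without the weak arrays, where SEC61A1 went from 0.66 to 0.21 and MANF from 0.55 to 0.12. Ribosomal protein genes were higher for 14 of 15, with a median of 0.28 (adjusted p = 0.00153, adjusted p = 0.655 with an estimated correlation), RPL35 at 0.39 (0.24 without the weak arrays) and RPL8 at 0.38. Extracellular matrix genes were higher for 15 of 18, with a median of 0.24 (adjusted p = 0.012, adjusted p = 0.529 with an estimated correlation), COL6A3 at 0.74 and PLAT, which encodes tissue plasminogen activator, at 0.84. Their median was 0.47 without the weak arrays. Macrophage markers were higher for 6 of 10, with a median of 0.28 (adjusted p = 0.0211, adjusted p = 0.529 with an estimated correlation), C1QA at 0.80 (0.52 without the weak arrays) and LYZ at 1.04. Without the weak arrays 10 of 10 macrophage markers were higher, with a median of 0.55. Genes of prostaglandin synthesis and its receptors were lower for 12 of 14, with a median of -0.54 (adjusted p = 0.0275, adjusted p = 0.305 with an estimated correlation), the thromboxane synthase gene TBXAS1 at -1.60 ± 0.59 and the cyclooxygenase gene PTGS1 at -1.44 ± 0.56. Their median was -0.03 without the weak arrays, with TBXAS1 at -0.74 and PTGS1 at -0.90.

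Quantile normalization moved the median of all genes from -0.06 to 0.27 in the averaged comparison. It left only the call of the prostaglandin list (adjusted p = 0.0108) and ended those of oxidative phosphorylation (0.358), the secretory list (0.358), ribosomal proteins (0.713), extracellular matrix (0.563) and macrophage markers (0.0905). The prostaglandin median was -0.23 with it and -0.17 with normexp correction, and the ribosomal and macrophage medians were 0.16 and 0.79 with it. Over all genes 0 members of these lists passed, and adjusted over the list alone 2 macrophage markers and 0 genes of the others passed. On scan days 1 and 2 the averaged means were 0.52 and 0.13 for oxidative phosphorylation, 0.45 and 0.12 for the secretory list, 0.58 and -0.10 for ribosomal proteins, 0.31 and 0.24 for extracellular matrix, 0.13 and 0.36 for macrophage markers and -0.55 and -0.59 for prostaglandin genes. The scan day 1 values cannot be told apart from the slide. With the slide as a block, macrophage markers (adjusted p = 0.0029, adjusted p = 0.359 with an estimated correlation) and prostaglandin genes (adjusted p = 0.02, adjusted p = 0.256 with an estimated correlation) passed, and ribosomal proteins turned to lower (adjusted p = 0.205). Receptivity genes, whose median was -0.11 without the block, metallothioneins and complement also passed there as higher, and with an estimated correlation the smallest adjusted p of all lists was 0.256. Leaving out the weak arrays gave an adjusted p of 0.0798 for oxidative phosphorylation, 0.183 for the secretory list and 0.128 for prostaglandin genes. The other 3 lists passed in that fit, macrophage markers with an adjusted p of 7.99e-07 (adjusted p = 0.148 with an estimated correlation), and 4 more lists were gained. Natural killer markers were higher for 9 of 9 (median 0.70, adjusted p = 0.000118, adjusted p = 0.178 with an estimated correlation), T and B cell markers for 4 of 5 (0.60, adjusted p = 0.00554, adjusted p = 0.152 with an estimated correlation) and neutrophil markers for 5 of 5 (0.40, adjusted p = 0.0356, adjusted p = 0.279 with an estimated correlation). Cholesterol synthesis genes had a median of -0.40 (adjusted p = 9.21e-06, adjusted p = 0.186 with an estimated correlation). With all arrays the medians of these 4 lists were 0.06, 0.19, -0.30 and -0.12, and none passed. The 6 lists became 3 without conception day 2 replicate 1 and 3 without non-mated day 2 replicate 1.

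The interaction asked whether the difference between cycle types changed with the day. ARID5B, TMEM61, SENP2, MTARC2, GADD45A, DOC2A, WARS and RGCC had the smallest p-values, each with a limma adjusted p of 0.986. By limma 0 genes passed and 167 had an unadjusted p under 0.05, and without the weak arrays 0 passed and 322 had an unadjusted p under 0.05.

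The next question was how the endometrium changed from day 2 to day 6 within each cycle type. In non-mated cycles IL6 lay at -4.01 ± 1.04 (SE, n = 4 against 4, limma adjusted p = 0.765), LIF at -2.76 ± 0.94 and PAEP at -1.50 ± 0.79, with SPP1 at 0.74 (adjusted p = 0.83). SPP1 lay at 1.17 without the weak arrays. Cell cycle genes were lower at day 6 for 20 of 22 members, with a median log2 difference of -1.04 (camera adjusted p = 0.000449, adjusted p = 0.67 with an estimated correlation), the mitotic genes BUB1 at -2.28 ± 0.96 and NUSAP1 at -2.38 ± 1.04. Progesterone receptor pathway genes were higher for 15 of 19, with a median of 0.44 (adjusted p = 0.000623, adjusted p = 0.67 with an estimated correlation). PER1 lay at 1.56 with and 0.65 without the weak arrays, and TSC22D3, a glucocorticoid-induced gene, at 1.09 and 0.34. Immediate early and heat shock genes were higher for 9 of 12, with a median of 0.52 (adjusted p = 0.00878, adjusted p = 0.112 with an estimated correlation), JUN at 1.5 and HSPH1 at 1.10 (0.23 without the weak arrays). Cytokine genes were lower for 11 of 13, with a median of -0.75 (adjusted p = 0.0257, adjusted p = 0.67 with an estimated correlation).

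Oxidative phosphorylation genes were higher at day 6 of non-mated cycles for 18 of 20 (median 0.37, adjusted p = 0.000505, adjusted p = 0.67 with an estimated correlation), SDHA at 0.96 and UQCRH at 0.71. Secretory pathway genes were higher for 15 of 20 (median 0.14, adjusted p = 0.0102, adjusted p = 0.67 with an estimated correlation), HERPUD1 at 1.16 and SEC61A1 at 1.05. Ribosomal protein genes were higher for 12 of 15 (median 0.23, adjusted p = 0.0469, adjusted p = 0.67 with an estimated correlation), RPS6 at 1.12 and RPS15 at -0.59. In the fit without the weak arrays the camera direction of these 3 lists turned to lower, with medians of -0.07, 0.00 and -0.06 (adjusted p = 0.468, 0.972 and 0.507). There SDHA lay at 0.33, UQCRH at 0.13, HERPUD1 at 0.49, SEC61A1 at 0.23 and RPS15 at -0.28. RPS6 rested on non-mated day 6 replicate 4, where its level was 7.89 against 3.78 to 4.45 on the other 3 arrays, and lay at 0.20 without that array. The cytokine median without the weak arrays was -0.33 (adjusted p = 0.185). With quantile normalization the camera direction of the oxidative phosphorylation and ribosomal lists turned to lower (adjusted p = 0.957 each), while their medians were 0.19, and of the 7 lists only cell cycle passed (median -0.27, adjusted p = 0.000749). With normexp correction the cytokine median was -0.30 (adjusted p = 0.125), the secretory median 0.39 and the ribosomal median 0.60, and with the deposited value table ribosomal proteins did not pass (adjusted p = 0.0805).

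The median of all genes went from -0.19 to 0.48 with quantile normalization. By limma 0 genes passed between days 6 and 2 of non-mated cycles and 396 had an unadjusted p under 0.05, and without the weak arrays 0 passed and 223 had one. The day F-test called 0 genes, with 301 at an unadjusted p under 0.05, and without the weak arrays 0 with 185. Adjusted over the list alone, 2 cytokine genes and 0 genes of the other lists passed. On slide 5, with the weak array, and slide 6, without it, the means were -1.77 and -0.85 for cell cycle, 1.01 and 0.24 for the progesterone receptor pathway, -3.12 and -0.52 for cytokines, 1.54 and 0.22 for oxidative phosphorylation, 1.07 and -0.00 for the secretory list, 0.81 and 0.21 for ribosomal proteins and -0.03 and -0.16 for immediate early genes. With the slide as a block cytokines had an adjusted p of 0.0602 and the other 6 lists passed, as did epithelial markers (higher, adjusted p = 0.0265), and with an estimated correlation the smallest adjusted p was 0.567. That fit keeps the weak array on slide 5. With the block and without the weak arrays, only ribosomal proteins of the 6 lists passed camera (adjusted p = 0.00776). There the adjusted p was 0.534 for cell cycle and 0.81 for the secretory list. It was 0.0516 each for the progesterone receptor pathway, oxidative phosphorylation and immediate early genes. Without the block, the fit without the weak arrays gained 5 lists in non-mated cycles. Natural killer markers were higher at day 6 for 9 of 9 (median 0.79, adjusted p = 1.35e-05, adjusted p = 0.139 with an estimated correlation), endothelial markers for 9 of 9 (0.52, adjusted p = 0.000445, adjusted p = 0.27 with an estimated correlation) and angiogenesis genes for 14 of 16 (0.31, adjusted p = 0.00208, adjusted p = 0.236 with an estimated correlation). Cholesterol synthesis genes (median -0.51, adjusted p = 0.000156) and estrogen response genes (-0.34, adjusted p = 0.0343) were lower, each with an adjusted p of 0.236 with an estimated correlation. With all arrays the medians of these 5 lists, in the same order, were -0.00 (4 of 9 higher), 0.14, -0.15, -0.00 and -0.20, and none passed.

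In conception cycles TMEM61, named LOC717082 in the files, fell from day 2 to day 6, with a log2 difference of -3.60 ± 0.57 (SE, n = 4 against 4, limma adjusted p = 0.0274). Its level was -1.42 ± 0.80 (SD, n = 4) at day 2 and -5.02 ± 0.94 at day 6, where it was well above background on 1 of 4 arrays, so the size of the fall is uncertain. Its probe lies on chromosome 1 from 57846192 to 57846251 (rheMac2). CFAP100, named LOC716433 in the files, fell by 3.34 on the log2 scale with an SE of 0.56 (adjusted p = 0.0327), with 3 of 4 day 6 arrays well above background, and its probe lies on chromosome 2 from 46212185 to 46212244. With normexp correction the differences were -2.16 for TMEM61 and -2.04 for CFAP100, and neither passed. CFAP100 did not pass the day F-test and is outside the naming rule, so it was chosen after its values were seen. PAEP lay at -0.28, LIF at -1.08 and SPP1 at -0.08 (adjusted p = 0.998 each). By limma 2 genes passed, both lower at day 6, and 508 had an unadjusted p under 0.05. The day F-test called 1 gene, with 270 at an unadjusted p under 0.05.

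Without the weak arrays, 208 genes passed between days 6 and 2 of conception cycles, 157 higher and 51 lower at day 6, and the day F-test called 52. With the scan range as a block 27 genes passed, 17 higher and 10 lower, and the day F-test called 0. With the slide as a block, within which the scan range does not vary, both counts stayed close to or above those without a block. A single range was used on 3 of 4 day 2 arrays and 1 of 4 day 6 arrays. Of 35 splits of these 8 arrays 2 called as many genes as the real 208, with a highest other of 246, so chance cannot be excluded. No array of either group was left out in that fit, which changes only the shared estimate of the spread. In it the highest differences were those of CCDC27 at 2.86 ± 0.47 (limma adjusted p = 0.0132), the connexin gene GJA3 at 2.76 ± 0.51, CD99L2 at 2.49 ± 0.46, YJEFN3 at 2.46 ± 0.45, the kinase scaffold gene MAPK8IP3 at 2.31 ± 0.38, DKKL1 at 2.24 ± 0.40, GRIN1, a glutamate receptor subunit gene, at 2.19 ± 0.41 and the leukocyte gene LSP1 at 2.08 ± 0.40. The lowest were PNMT, which encodes the enzyme that makes adrenaline, at -3.87 ± 0.81 (adjusted p = 0.0241), TMEM61, CFAP100, GCHFR at -3.25 ± 0.65 and CYB5R1 at -3.10 ± 0.67. After them came HRH1 at -2.99 ± 0.45 (floored fold 2.65), PIWIL4 at -2.29 ± 0.43 (floored fold 3.78) and RIPOR2 at -2.02 ± 0.43 (floored fold 1.48).

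Slides 7 and 8 each held 1 conception array of day 2 and 1 of day 6. TMEM61 differed by -4.08 and -2.27 there, and CFAP100 by -3.66 and -3.38. On scan days 1 and 2 the differences were -3.18 and -4.03 for TMEM61 and -3.52 and -3.16 for CFAP100. With the slide as a block the differences were -3.71 ± 0.83 for TMEM61 (adjusted p = 0.64) and -3.54 ± 0.62 for CFAP100 (adjusted p = 0.387), so the calls ended as the errors grew and the residual degrees of freedom fell from 18 to 10. TMEM61 had an adjusted p between 0.0751 and 0.195 without conception day 2 replicate 2, 3 or 4, or conception day 6 replicate 1, 2 or 3. CFAP100 had an adjusted p between 0.0516 and 0.266 without any of these, or without conception day 4 replicate 1, non-mated day 2 replicate 1 or 2, non-mated day 4 replicate 1, or non-mated day 6 replicate 2 or 3. Without conception day 6 replicate 4 the count was 4.

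Natural killer cell markers were higher at day 6 of conception cycles for 8 of 9 members, with a median log2 difference of 1.11 (camera adjusted p = 0.00296, adjusted p = 0.798 with an estimated correlation), the receptor gene KLRC1 at 1.59 ± 0.88 and the granzyme gene GZMA at 1.27 ± 0.75. Cholesterol synthesis genes were lower for 15 of 15, with a median of -0.67 (adjusted p = 0.00265, adjusted p = 0.798 with an estimated correlation), PMVK at -1.03 ± 0.40 and MVK at -0.85 ± 0.41, both kinases of the mevalonate pathway. Glycolysis and hypoxia genes were lower for 15 of 17, with a median of -0.77 (adjusted p = 0.0135, adjusted p = 0.798 with an estimated correlation), PGAM1 at -0.90. NDRG1, a gene induced by hypoxia, went against its list at 2.99 ± 0.83 (limma adjusted p = 0.773, and 0.0278 without the weak arrays). Cell cycle genes were lower for 19 of 22, with a median of -0.81 (adjusted p = 0.0152, adjusted p = 0.991 with an estimated correlation), AURKA at -1.35 and CCNB1 at -1.38. Ciliated cell markers were lower for 8 of 9, with a median of -0.63 (adjusted p = 0.0466, adjusted p = 0.798 with an estimated correlation), RSPH1 at -1.45 and DNAI2 at -1.14, both genes of the ciliary axoneme. Ribosomal protein genes were higher for 13 of 15, with a median of 0.47 (adjusted p = 0.00851, adjusted p = 0.898 with an estimated correlation), RPS16 at 0.88 and RPS19 at 0.63.

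Normexp correction moved the median of all genes from -0.02 to -0.18. With it the natural killer median was 0.56, with an adjusted p of 0.0147, and the cell cycle (adjusted p = 0.129), glycolysis (0.0579) and ciliated (0.0546) lists did not pass. With quantile normalization the ribosomal median was 0.08 (adjusted p = 0.548), and ciliated markers did not pass (adjusted p = 0.0776). Over all genes 0 members of these lists passed, and adjusted over the list alone 1 glycolysis gene and 0 genes of the others passed. On slides 7 and 8 the means were 1.13 and 1.22 for natural killer markers, -0.91 and -0.09 for cholesterol synthesis, -1.0 and -0.70 for glycolysis, 0.26 and -0.49 for cell cycle, -0.72 and -0.54 for ciliated markers and 0.92 and 0.34 for ribosomal proteins. With the slide as a block cell cycle (adjusted p = 0.941) and ciliated markers (adjusted p = 0.0534) did not pass, oxidative phosphorylation passed as higher (adjusted p = 0.00837), and with an estimated correlation the smallest adjusted p was 0.983. The natural killer and cholesterol lists moved the same way in non-mated cycles once the weak arrays were left out. The difference between the cycle types in the change from day 2 to day 6 had a camera adjusted p of 0.442 for natural killer markers and 0.0666 for cholesterol synthesis, and of 0.64 and 0.47 without the weak arrays. Cell cycle without the weak arrays had an adjusted p of 0.147 and ciliated markers of 0.223. The 6 lists became 3 without conception day 2 replicate 3 and 3 without conception day 6 replicate 1.

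For some lists that did not pass, the median, the mean and the camera direction differed in sign. At day 2 these were the interferon, angiogenesis, Wnt, complement, natural killer and macrophage lists. At day 4 they were the progesterone receptor, estrogen, decidualization, interferon, angiogenesis, Wnt, cholesterol, epithelial, stromal and lymphocyte lists, and at day 6 the decidualization, cytokine, adhesion and Wnt lists. Averaged over days they were the receptivity, estrogen, Wnt, glycolysis and smooth muscle lists. From day 2 to day 6 they were the interferon, angiogenesis, Wnt, stromal and natural killer lists in non-mated cycles and the extracellular matrix, angiogenesis, complement and macrophage lists in conception cycles.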

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

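The tests of PIWIL4 and its companion genes against the weak arrays and the slide, the test of the oxidative phosphorylation list without the weak arrays, the counts without the weak arrays and the splits that keep the slides were chosen only after the results were seen. The rules for reading the scan range test, the slide test of the oxidative phosphorylation list, the weak array and slide tests of PIWIL4 and its companions, and splits with a real count of 0 were changed after their values were seen, each towards a less firm reading.

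Of 336 groups of 4 arrays tested, 30 had an array whose gap to its nearest neighbour took up an unusually large part of the group's range, where chance gives about 1 in 20. Non-mated day 2 replicate 3, a weak array, was that array in 11 of the 30. There the gap as a share of the range was 0.940 for ILK, 0.833 for HTRA1, 0.838 for PER1, 0.855 for LIFR, 0.838 for ATF4, 0.867 for SEC61A1, 0.870 for SDHA, 0.925 for MANF, 0.951 for NDUFB9, 0.924 for TSC22D3 and 0.849 for UQCRH. On that array LIFR lay above the rest of its group and the other 10 genes lay below it. The LIFR level of -0.284 was the floor of the array, shared by PER1, so its signal was not high. The lowest signal there, 19.0, was also the median signal. Among other non-mated arrays the share was 0.914 for C1QA at day 2, 0.922 for HTRA1 and 0.910 for PTGS1 at day 4, and 0.858 for TEX29, 0.939 for ZBTB16 and 0.837 for RPS6 at day 6. Non-mated day 6 replicate 4 was the outlying array for TEX29, ZBTB16 and RPS6. In conception cycles it was 0.831 for ILK, 0.856 for MAIP1, 0.840 for MTARC2, 0.894 for DKKL1 and 0.842 for RIPOR2 at day 2, and 0.881 for TESC, 0.886 for RGCC and 0.886 for LYZ at day 4. At conception day 6 it was 0.920 for CFAP100, 0.859 for PTGS1 and 0.876 for COX4I1, where the outlying array was replicate 1, and 0.910 for IER3 and 0.862 for YJEFN3, where it was replicate 3.

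The difference between the cycle types in 5 lists changed between days by camera. The cell cycle list moved down from day 2 to day 4 (adjusted p = 0.00011) and up from day 4 to day 6 (adjusted p = 0.00011). The progesterone receptor pathway moved down from day 2 to day 6 (adjusted p = 0.00011) and from day 4 to day 6 (adjusted p = 0.0367). Glycolysis and hypoxia genes moved down from day 2 to day 4 (adjusted p = 0.00961) and from day 2 to day 6 (adjusted p = 0.00866). Immediate early and heat shock genes moved down from day 2 to day 6 (adjusted p = 0.0429) and metallothioneins from day 4 to day 6 (adjusted p = 0.049, and 0.0544 without the weak arrays). With an estimated correlation every one of these 8 tests had an adjusted p of at least 0.677. Further lists passed camera only without the weak arrays, where no estimated correlation was run. Ribosomal proteins moved up from day 2 to day 4 (adjusted p = 0.000112) and to day 6 (0.00707), and oxidative phosphorylation from day 2 to day 4 (0.0151). Endothelial and macrophage markers moved down from day 4 to day 6 (0.00707 each).

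PIWIL4, TMEM61, CFAP100 and HRH1 lay lower in conception cycles averaged over the days, and 3 technical or cellular explanations were tested. Averaged over days the differences without the weak arrays were -1.99 (SE 0.28, limma adjusted p = 0.0109) for PIWIL4 and -1.77 (SE 0.32, 0.110) for TMEM61. They were -1.79 (SE 0.36, 0.188) for CFAP100 and -1.87 (SE 0.29, 0.0209) for HRH1. No weak array enters their day 6 part. Over days 2 and 4 the mean differences of PIWIL4, TMEM61, CFAP100 and HRH1 were -1.73, -1.20, -1.24 and -1.64 with all arrays. Without the weak arrays, which then do not enter them, they were -1.49 (SE 0.35), -1.13 (SE 0.41), -1.34 (SE 0.47) and -1.43 (SE 0.37). Of these, 0 passed over all genes. At day 2 alone TMEM61 and HRH1 lay at 0.39 and 0.20 without the weak arrays, and at 0.01 and -0.48 with all arrays. PIWIL4, TMEM61 and HRH1 were well above background on only 6, 5 and 4 of 12 conception arrays. The genes were also picked with the weak arrays included. A partial contribution of the weak arrays at days 2 and 4 can therefore not be told apart. The slide cannot be told apart either, since with it as a block the averaged differences of these genes, picked for being low, were -1.74 (SE 0.42), -1.37 (SE 0.59), -2.41 (SE 0.45) and -1.72 (SE 0.48) in the same order, with an adjusted p of 1.00 each; for PIWIL4, at -2.15 (SE 0.28) without the block, the call ended as the difference shrank, its error grew and the residual degrees of freedom fell from 18 to 10. Fewer ciliated cells cannot be told apart either. The ciliated markers at day 6 had a median of -0.48 with an SD of 0.64 over 9 genes, with 8 of 9 lower. Their median stayed above the bound of -1.35, but that bound was set by CFAP100, a gene picked for being low, so the test cannot decide. A biological difference between the cycle types stays open as a hypothesis, beside the slide, fewer ciliated cells and, for a part of the difference at days 2 and 4, the weak arrays. The scan range, which partly goes with the cycle type, was not among the explanations tested for these genes.

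Without the weak arrays 157 genes, 90 of them named, were higher at day 6 than at day 2 of conception cycles, with a median of 1.82, and 120 of them were well above background on all 8 arrays. A trend with probe GC content shared by all features is argued against as the whole cause, since 141 of the 157 were still called after each array's trend was removed. In all, 200 genes were then called higher and 89 lower. The median GC of the 157 genes, 58.3%, lay above the 41.7% of all features. They were picked in the same arrays, and an effect of GC stronger in them than the shared trend would remain, so GC content is not excluded. The scan range was not told apart from the day, since 3 of 4 day 2 arrays had a single range. Extended minus single range was 0.87 (spread 0.24) at conception day 4 and 0.01 (spread 1.24) at non-mated day 2, each with 1 array of single range. Far fewer genes passed with the scan range as a block. With the slide as a block, within which the scan range does not vary, the count stayed close to the full one. Which of the 157 genes passed there is not reported, so the blocks do not decide. Low signal over background cannot be told apart either, with a Pearson r of -0.33 between level and percent well above background over 13 other arrays (permutation p = 0.262), a Spearman rho of -0.21 (permutation p = 0.508) and an r of -0.18 without the 2 farthest arrays. On weak arrays these genes had median levels of 1.88 on non-mated day 2 replicate 3 and 3.49 on day 4 replicate 2, against -2.24 and -0.34 at conception days 2 and 6, so a technical share is a candidate explanation and a biological change with the day stays open.

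Oxidative phosphorylation genes lay higher in conception cycles at day 2, with a median of 0.43. The camera adjusted p without the weak arrays was 0.675 and the median -0.04, which is what the weak array of non-mated day 2 as the source would give. The slide cannot be told apart from it, since slide 4, where the mean difference was 0.0477, also holds no weak array. No biological explanation was tested for this list.

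Other splits of the same arrays were counted for each result. For the averaged comparison, 4 of 100 splits, the real one included, called as many genes as the real 1, with a highest other of 76 genes. That share is under 0.05 only among splits that take no account of the slide, and it is not corrected for the number of comparisons. Among 100 splits that keep the slides, made by exchanging whole slides or arrays of 1 slide and day, 6 called as many, with a highest other of 12, so chance cannot be excluded with the slides kept, and with the slide as a block the count was 0. For day 6 against day 2 in conception cycles, 1 of 35 splits called as many as the real 2, with a highest other of 0. That is the smallest share 35 splits can give. It takes no account of the slide and is not corrected for the number of comparisons, so chance is not excluded. Of the 35 splits only 4 keep the slides, too few for a share under 0.05, with a real count of 2 and a highest other of 0. The count there was 0 with the slide as a block, where TMEM61 and CFAP100 still differed by -3.71 (SE 0.83) and -3.54 (SE 0.62), and 0 without conception day 2 replicate 2, 3 or 4 or conception day 6 replicate 1, 2 or 3. Chance cannot be excluded for the count at day 6, where 2 of 35 splits called as many as the real 1, with a highest other of 2, nor for the effect of day in conception cycles, with 8 of 100, a real count of 1 and a highest other of 49. Where the real count was 0 the splits decide nothing, since any split gives as many: 35 of 35 at day 2 (highest other 0), day 4 (highest other 0) and day 6 against day 2 in non-mated cycles (highest other 1), and 100 of 100 for the interaction (highest other 62) and the effect of day in non-mated cycles (highest other 2543). The split with 2543 genes put the 3 weak arrays together, and splits that call many genes, including those with 76, 62 and 49, point to a structure of the samples.

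For the lists chance cannot be excluded either. As many lists as the real split were called by 10 of 35 splits at day 2 (real 9, highest other 12), 27 of 35 at day 4 (real 2, highest other 8), 20 of 35 at day 6 (real 4, highest other 11) and 40 of 100 averaged over days (real 6, highest other 14). From day 2 to day 6 they were 13 of 35 in non-mated cycles (real 7, highest other 11) and 16 of 35 in conception cycles (real 6, highest other 11). Without the weak arrays, 2 of 35 splits of the conception arrays of days 2 and 6 called as many genes as the real 208, with a highest other of 246, so chance cannot be excluded there. That split set day 2 replicates 1, 2 and 4 with day 6 replicate 1 against day 2 replicate 3 with day 6 replicates 2, 3 and 4. It exchanges only day 2 replicate 3 and day 6 replicate 1, both of extended scan range. The scan ranges are thus divided between its sides as in the real split, and the other arrays keep their day. Its count does not tell the scan range, the day or another structure of the samples apart.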

How the results depend on the processing

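The fits without the weak arrays were chosen only after the results were seen, and the other alternatives were planned. Counts are of genes past the threshold by limma, and with all arrays and the settings of the report they were 0, 0 and 1 at days 2, 4 and 6, 1 averaged over days, 0 for the interaction, 1 for the effect of day in conception cycles and 0 in non-mated cycles, and for day 6 against day 2, 2 in conception and 0 in non-mated cycles. Lists past camera were 9, 2, 4 and 6 at days 2, 4, 6 and averaged, and from day 2 to day 6, 7 in non-mated and 6 in conception cycles.

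All gene counts were 0 with normexp background correction, quantile normalization, only probes well above background on all 24 arrays, the slide as a fixed block, or only slides with both cycle types. Without a filter on dim probes the averaged count was 1 and the others 0. With normexp 8 lists passed at day 4. With quantile normalization the lists were 0 at day 2, 0 at day 4, 1 averaged and 1 in non-mated cycles. With the slide as a fixed block they were 2 at day 2 and 5 at day 4. On slides with both cycle types they were 0 at day 4, 10 at day 6, 2 averaged and 4 in non-mated cycles. A scan day block gave 0 genes at day 6 and 2 averaged, and a slide as a random block, a change of at least 2-fold, every probe on its own and the deposited value table left all gene counts as they were. With the groups compared alone in the fit, 0 genes passed at day 6, 0 for the effect of day and 128 (117 higher, 11 lower) for day 6 against day 2 in conception cycles; this was not run for the averaged comparison and the interaction, which use all groups. Array weights gave 1 gene at day 2, 12 at day 6, 4 averaged, 1 for the interaction, 49 for the effect of day in conception cycles and 203 (108 higher, 95 lower) for day 6 against day 2, where the report's 2 were both lower. Limma-trend with robust eBayes gave 0 at day 6 and 2 for the effect of day. With an estimated correlation and with fry, 0 lists passed in all 6 comparisons. The cause of these changes was not tested, except that fewer arrays or probes enter some fits.

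With the replicate block 0 genes passed at day 6 and 1 for day 6 against day 2 in conception cycles, and no other count moved over 1.5 times. The labels state no pairing by number, and the rule that every pair of the same number correlate over 0.1 was not met, with 20 of 60 pairs (median 0.0181). However, 12 of 24 arrays were closest to one of their own number, more than an even draw would give. Conception replicates 3 and 4 of each day also lay on slides 7 and 8, so a structure shared by number is not excluded.

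Without the 3 weak arrays 3 genes passed at day 6, 2 averaged, 52 for the effect of day in conception cycles and 208 for day 6 against day 2, and 3 lists passed at day 2 and 8 at day 4. With only probes well above background on the other 21 arrays as well, the counts were 0 at day 6, 0 averaged, 62 and 161. With a scan range block as well they were 0 at day 6, 2 averaged, 0 and 27, with 5, 8 and 2 lists at days 2, 4 and 6. With a slide block as well they were 0, 0, 67 and 194, with 6 lists at day 4, 7 at day 6, 12 averaged, and 1 in non-mated cycles.

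Leaving out each array in turn moved the counts from 0 to 1 at day 4, 0 to 4 at day 6, 1 to 4 averaged, 0 to 3 for the effect of day in conception cycles and 0 to 4 for day 6 against day 2 in conception cycles, and left the others at 0. The effect of day went to 0 without conception day 2 replicate 2, 3 or 4, day 4 replicate 4 or day 6 replicate 1, 2 or 3, to 2 without conception day 4 replicate 3, day 6 replicate 4 or non-mated day 6 replicate 4, and to 3 without non-mated day 2 replicate 3. Lists ranged from 4 to 10 at day 2, 2 to 6 at day 4, 2 to 8 at day 6, 3 to 7 averaged, 5 to 8 in non-mated and 3 to 6 in conception cycles. The arrays behind the other changes are named beside each result in the report. Over 231 values of named genes and 9629 alternatives, 59 no longer passed, 100 newly passed, 202 that did not pass moved by over 1 SD and 9268 did none of these. The sign changed in 142, none of which passed with or without the alternative. PIWIL4 passed in 16 of 41 alternatives at day 6 (log2 from -3.22 to -1.59) and 35 of 40 averaged (-2.26 to -1.15), TMEM61 in 30 of 41 (-4.06 to -2.16) and CFAP100 in 23 of 41 (-3.59 to -2.04). Signal over background limits the weak arrays, where 4.33% to 37.9% of probes were well above it.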

Other observations

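The counts without the weak arrays were chosen only after the results were seen. Marker lists with too few measured genes for a test are given as the number of arrays on which a gene was well above background, out of 12 in each cycle type. Among red blood cell genes, HBB, which encodes beta globin, was above on 12 conception and 11 non-mated arrays, AHSP on 12 and 10, and EPB42 on 0 and 5. Among squamous epithelial genes, KRT4 was above on 5 and 8 arrays and S100A7 on 2 and 5. Among semen and sperm genes, ODF1 was above on 12 and 11 arrays, SEMG1, a seminal fluid protein gene, on 0 and 2, PRM1, a sperm protamine gene, on 0 and 2, and TNP1 on 2 and 0. Among trophoblast and early embryo genes, POU5F1 was above on 9 and 9 arrays, GCM1 on 2 and 5, and CGA, the alpha subunit gene of gonadotropins, on 0 and 0. No test was run on these numbers.

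Probes of a gene did not move together for SLC2A3, whose probes differed by 0.77 and -0.83 between cycle types at day 6, nor for CSF3R, whose 3 probes differed by 0.09, 0.32 and -1.24. Probes of IL11RA, FDPS, IL6ST, GNLY, ENO2 and FBLN1 also disagreed. For these genes the value used was that of the probe with the highest mean. The 3 probes of GRIN1 differed by 2.19, 2.16 and 2.08 between days 6 and 2 of conception cycles.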
